A study of Mus musculus with 6 samples.

How the data were processed

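Total RNA from NIT-1 cells was labelled with biotin and read on 6 arrays, 3 of cells kept for 24 h with 4 µmol/L cadmium sulphate after 24 h in culture and 3 of cells without it, per the labels. The values deposited by the authors are 1 per transcript cluster and array. Their log2 scale is inferred from the deposited values, which lie in the range of a scanner on that scale. The base of the logarithm, the background correction, the normalization and the software are not given in the sources used here, so a fold change holds only if the base is 2. Array medians averaged 3.34 in control and 3.39 in cadmium arrays, and each cadmium median lay above each control median. The difference was 0.049 (exact permutation p = 0.1, the smallest that 3 against 3 allows). The values were used without further scaling, so counts of higher and lower genes depend on this offset. The table had 46478 rows, of which 39746 were transcript clusters and 6732 control probes. No scanner files were analysed here. The number of columns of values that no sample could be given was 0.

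Gene names came from the platform annotation, with symbols updated by gene identifier, symbol or synonym through the RefSeq annotation of assembly GRCm38.p6. Of the clusters, 19094 had 1 gene, 1051 had several and were not named, and 19601 had none in that annotation. The brightest probe stood for each gene, which left 18880 genes, of which 155 had over 1 probe. No coordinates are given, since the build of the probes is not given in the sources used here. Among the genes, 335 had values identical to another gene on all 6 arrays, in 84 distinct patterns, which occurs where copies of a gene share probes. Small nuclear RNA copies and pseudogenes of the same sequence are therefore uncertain. Levels were compared between probes to choose the brightest probe of a gene, in the rule for named genes and in filters on level. As a measure of expression they were set only against negative control probes, apart from the median levels of beta cell identity and protein-coding genes.

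Groups and replicate numbers came from the sample titles. The source names carry numbers of their own, which do not follow those of the titles. The labels call the samples biological replicates and do not say whether they came from separate passages or days, so p-values measure the spread between these cultures.

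Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) with Benjamini-Hochberg adjustment over 18880 genes and a threshold of 0.05. Gene lists, their names and the rule for named genes were set before the data were examined. The 29 lists held 685 entries, of which 351 were measured under a single gene name, and 28 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01. The tests were two-sided, and p-values were adjusted over the 28 lists. With an estimated correlation 0 of the 11 lists called by camera passed, and the lowest adjusted p was 0.185. With fry, which asks whether the genes of a list move one way on balance and compares with no other gene, 12 lists passed, 6 of which camera did not call. Fry was run on the deposited scale only, where the median change over all genes was 0.044, so that shift enters its calls. Of the lists camera called, fry did not pass cholesterol synthesis, the integrated stress response, the proteasome, G1/S and G2/M, at adjusted p of 0.106, 0.108, 0.177, 0.307 and 0.429. Counts adjusted over the list alone repeat the adjustment within each list.

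The named genes are the 12 largest increases and 12 largest decreases among genes past the threshold whose arrays did not overlap between groups and whose brighter group mean was at least the median level of 4.16, without predicted genes, small RNA families, olfactory and vomeronasal receptors and pseudogenes. Up to 4 members of each list with the lowest adjusted p were added, with 30 genes fixed beforehand, of which 17 were measured under a single name. Gclm, Hspa1a, Hspa1b, Ddit3, Ins1 and Sod1 are among the fixed genes not analysed here.

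Alternatives covered array centring, quantile normalization, filters on level, the probe that stands for a gene, the variance model, array weights, the replicate number as a block, each array left out in turn, a stricter threshold and a test against a minimum change of 0.26. The steps were tested on simulated data with the means and spreads of these 18880 genes and 200 changed genes. Of the simulated changes of 0.5 on the log2 scale 56% were called, of those of 1 98%, and of larger ones 100%. Unchanged genes made up 4.84% of the calls. The simulation was run once with independent noise for each gene and no deviation shared across an array. Its shares therefore do not carry over to the calls in the real data. Figures were drawn with matplotlib 3.10.9.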

Results

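Gene expression was measured with microarrays in NIT-1 cells, a line of mouse pancreatic beta cells, after 24 h in medium with 4 µmol/L cadmium sulphate or in medium alone. Each group had 3 arrays, labelled as biological replicates, and the number of arrays limits the precision of every value. The comparison asks which transcripts differ after a cadmium dose that the series describes as causing oxidative damage. Values are log2 signals for 18880 genes, given below as mean ± SD with n = 3 per group, and changes are cadmium minus control. The median signal of all transcript clusters was between 3.34 and 3.40 on every array, and higher on each cadmium array than on any control array. Positive control probes exceeded negative ones with an area under the curve of 0.837 to 0.850, and the area was lower on each cadmium array than on any control array. Signals correlated across genes at 0.995 to 0.997 within the control group, 0.995 to 0.997 within the cadmium group and 0.987 to 0.991 between groups. The first principal component, with 61.2% of the variance, separated the groups. Control replicate 3 and cadmium replicate 1 lay apart from the other arrays on the second component, which held 15.6%.

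With cadmium, 11 of 13 heat shock genes, 5 of 6 metallothionein and metal response genes and 10 of 14 Nrf2 targets rose, and 3 of 10 cholesterol synthesis genes and 6 of 11 genes of glycolysis and hypoxia fell. As lists these passed camera with a preset correlation but not with an estimated correlation, where adjusted p = 0.185 to 0.555. The largest measured increase under the rule was in Hsph1, a cytosolic chaperone of the Hsp110 family, from 5.44 ± 0.12 to 8.50 ± 0.24, which is at least 4.97-fold (limma adjusted p = 0.0002), with the control mean below the background bound of 6.18. Chordc1, an Hsp90 co-chaperone, rose at least 4.24-fold from 5.85 ± 0.17 to 8.27 ± 0.31. Hmox1, which degrades haem, rose at least 2.62-fold from 5.41 ± 0.26 to 7.58 ± 0.26. Mt2, a metallothionein that binds cadmium and zinc, rose 4.45-fold from 7.94 ± 0.28 to 10.09 ± 0.11. The platelet-derived growth factor gene Pdgfc had the largest measured decrease under the rule, from 7.74 ± 0.02 to 6.03 ± 0.12, at least 2.98-fold lower with cadmium (limma adjusted p = 0.0002). Folds are ratios of signals. The bound is the mean over arrays of the 95th percentile of negative control probes. Of the 24 genes with the largest changes, 8 had both group means above it, 12 had 1 and 4 had 0 (Akr1b8, Lgr4, Slc39a10 and Aass), and no fold is given where both means lay below. Where 1 mean lay below, a fold is given only as a lower bound, the dimmer group's arrays being set to at least the 95th percentile of their own negative controls. Whether a negative control value stands for a single probe, while a gene's value combines several, is not given in the sources used here, so the bound is approximate.

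In all, 2302 genes changed at a limma adjusted p under 0.05, of which 1222 were higher and 1080 lower with cadmium. Among them 188 changed at least 2-fold, 164 upward and 24 downward. On the deposited scale the groups did not overlap in 35.9% of all genes, where chance gives 10% for a single gene with 3 against 3. The offset between array medians and deviations shared across an array enter this share. No share with arrays centred is given, so the excess over 10% is not a measure of the effect of cadmium alone. Of the 2302 called genes 513 had both group means above the bound, 244 had 1 and 1545 had 0. The measured change was under 1.5-fold in 75.4% of all called genes and in 56.7% of the 513, and where means lay below the bound changes may be compressed, which holds for counts of 2-fold changes and for medians of lists too. The share of higher genes among those called was 53.1% in the deposited scale, 35.6% with each array centred on its median and 39.9% after quantile normalization. The count fell to 1181 without control replicate 1, 1139 without control replicate 2, 1145 without cadmium replicate 2 and 1178 without cadmium replicate 3. Of the single genes named below, Gpx1, Prdx4, Mt4, Gstm1, Psmd4, Ldha, Pdk1, Atr, Plk3, Ireb2, Lpcat3, Slc30a9, Slc30a7 and Mff also lost their calls when at least 1 of the 6 arrays was left out.

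**Figure D1:**
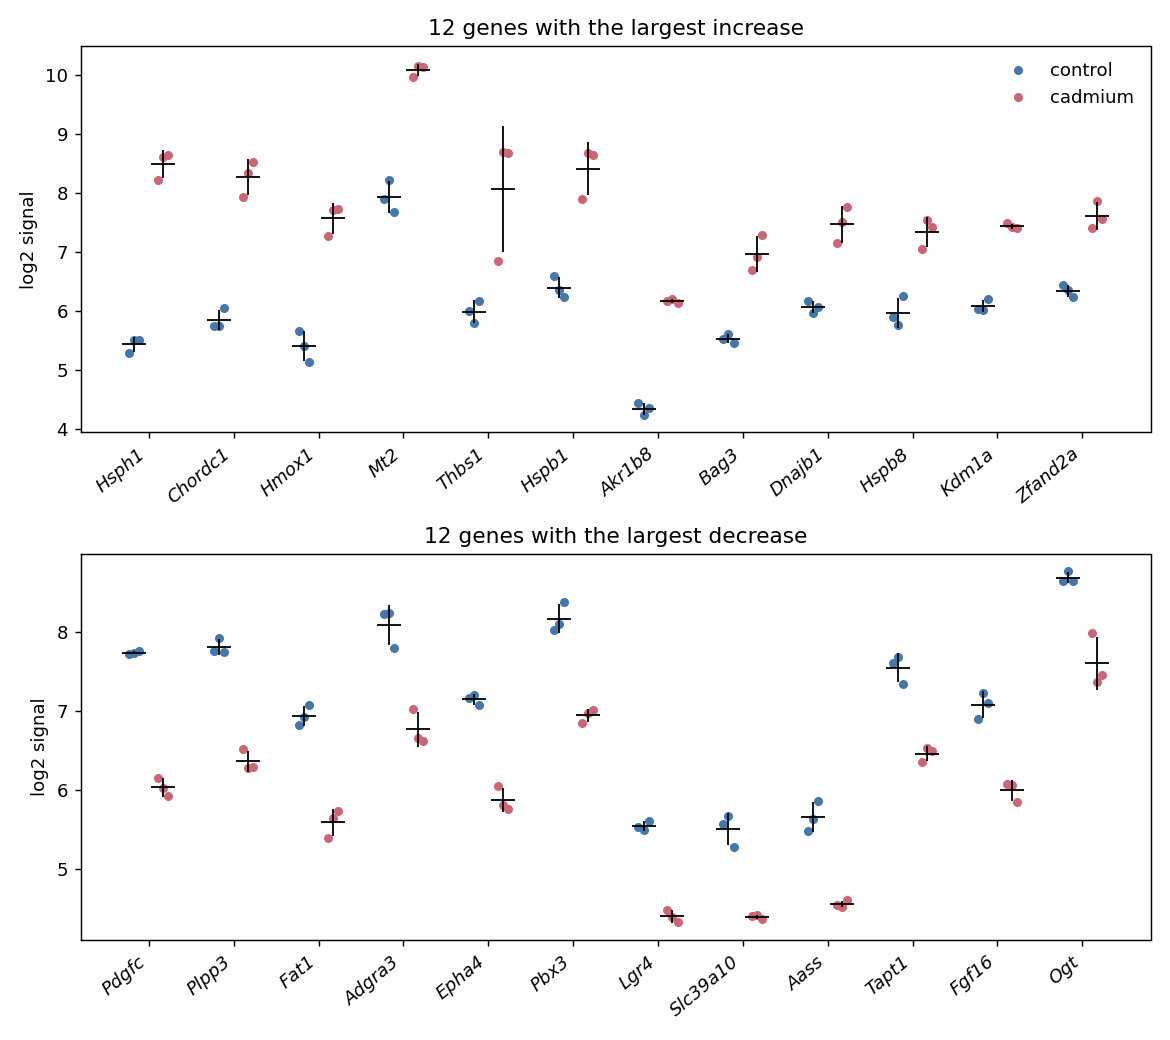
Log2 signal of the 12 genes with the largest increase (top) and the 12 with the largest decrease (bottom) under the naming rule. Points are single arrays, 3 per group, horizontal marks are group means and vertical bars are SD. Hsph1 moved from 5.44 to 8.50 and Pdgfc from 7.74 to 6.03, and in Thbs1 the cadmium arrays had an SD of 1.07.

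Among the other genes with the largest increases, the small heat shock protein genes Hspb1 and Hspb8 rose 4.03-fold and at least 2.17-fold. The co-chaperone genes Bag3 and Dnajb1 rose at least 1.73-fold and at least 2.45-fold. Akr1b8, an aldo-keto reductase, rose from 4.35 ± 0.10 to 6.17 ± 0.03. Zfand2a, an arsenite-inducible proteasome-associated protein, rose 2.41-fold, and Kdm1a, a histone lysine demethylase, rose at least 2.36-fold. Thbs1, encoding thrombospondin, rose at least 3.67-fold but varied among the cadmium arrays, at 8.08 ± 1.07 against 6.00 ± 0.19. Its call was lost, with an adjusted p of up to 0.105, when any 1 array except cadmium replicate 1 was left out.

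Among the other genes with the largest decreases, the lipid phosphatase gene Plpp3 had a 2.73-fold lower level with cadmium, at 6.36 ± 0.13 against 7.81 ± 0.10. The atypical cadherin Fat1 was at least 1.71-fold lower, the adhesion receptor Adgra3 2.50-fold lower and the ephrin receptor Epha4 at least 1.98-fold lower. The homeobox gene Pbx3 was 2.34-fold lower. Lgr4, a receptor for R-spondins, fell from 5.55 ± 0.06 to 4.40 ± 0.08, Slc39a10, a zinc importer, from 5.51 ± 0.21 to 4.39 ± 0.02, and Aass, of lysine degradation, from 5.66 ± 0.19 to 4.55 ± 0.04. Tapt1 was 2.12-fold lower, as was Ogt, the O-GlcNAc transferase, and Fgf16 was at least 1.88-fold lower.

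The heat shock list rose: 11 of its 13 measured members were higher, 12 adjusted over the list alone, and 0 were lower. The median change was 1.00 (camera adjusted p = 2.1e-10, and adjusted p = 0.508 with an estimated correlation). Besides the genes above, the mitochondrial co-chaperonin gene Hspe1 rose by 1.00 ± 0.08 (SE), from 6.73 ± 0.05 to 7.73 ± 0.13 (limma adjusted p = 0.0015).

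The list of metallothioneins and metal response genes also rose, with 5 of 6 members higher both over all genes and adjusted over the list alone (camera adjusted p = 0.00018, and adjusted p = 0.344 with an estimated correlation). Slc30a1, which exports zinc from the cell, rose from 5.02 ± 0.04 to 5.92 ± 0.12 (limma adjusted p = 0.0015). Mt1 rose at least 1.37-fold from 5.77 ± 0.09 to 6.64 ± 0.17. Mt4, another metallothionein, rose from 4.77 ± 0.28 to 5.69 ± 0.26, below the bound in both groups.

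Targets of Nrf2, the transcription factor of the antioxidant response, rose in 10 of 14 cases, 12 adjusted over the list alone, and 0 fell (camera adjusted p = 1.6e-07, and adjusted p = 0.185 with an estimated correlation). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose 1.99-fold from 6.85 ± 0.02 to 7.84 ± 0.20. The cystine transporter gene Slc7a11 rose from 3.83 ± 0.15 to 4.67 ± 0.12. Srxn1, sulfiredoxin, rose from 6.07 ± 0.01 to 6.66 ± 0.09. In the list of glutathione transferases 3 of 16 members rose, 3 adjusted over the list alone, with Gstm1 at 0.28 ± 0.05 (SE) (camera adjusted p = 0.031, and adjusted p = 0.637 with an estimated correlation). That list did not pass without control replicate 3, cadmium replicate 2 or cadmium replicate 3, at adjusted p of 0.065, 0.084 and 0.112, nor among genes at or above the median level, at 0.182.

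Among antioxidant enzymes Cat and Gpx1 rose and Prdx4 fell, and the counts adjusted over the list alone were the same, 2 higher and 1 lower of 7 (camera adjusted p = 0.438). Cat, catalase, rose from 5.76 ± 0.07 to 6.19 ± 0.06.

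The list of Atf4 targets and the integrated stress response rose, with 4 of 17 members higher, 7 adjusted over the list alone, and 0 lower (camera adjusted p = 0.0034, and adjusted p = 0.637 with an estimated correlation). Atf3 rose at least 1.41-fold from 5.63 ± 0.11 to 6.69 ± 0.23, and Ppp1r15a, which directs dephosphorylation of eIF2α, rose from 4.57 ± 0.06 to 5.13 ± 0.13, below the bound in both groups. Trib3 was at 5.54 ± 0.30 and 5.85 ± 0.06, also below it, and did not pass. Of 7 chaperones of the endoplasmic reticulum 0 passed, also adjusted over the list alone, with Hspa5 at 6.24 ± 0.05 and 6.37 ± 0.22 (camera adjusted p = 0.226). Without cadmium replicate 1, an array that stood apart, that list was lower, with a median of -0.24 (camera adjusted p = 0.0024). The proteasome list rose, with 2 of 16 subunits higher, 5 adjusted over the list alone, among them Psmd4 at 0.30 ± 0.07 (SE) (camera adjusted p = 0.0073, and adjusted p = 0.679 with an estimated correlation). Without cadmium replicate 2 or cadmium replicate 3 it did not pass, at adjusted p of 0.079 and 0.081.

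Cholesterol synthesis genes fell as a list, with 3 of 10 lower, 6 adjusted over the list alone, and 0 higher (camera adjusted p = 0.0002, and adjusted p = 0.555 with an estimated correlation). Cyp51, lanosterol demethylase, fell from 6.44 ± 0.44 to 5.42 ± 0.18, and Fdps, farnesyl diphosphate synthase, from 6.91 ± 0.48 to 6.07 ± 0.07. Leaving out any 1 array except control replicate 3 ended both calls, with adjusted p of up to 0.080 for Cyp51 and 0.136 for Fdps.

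Genes of glycolysis and the hypoxia response fell as a list, with 6 of 11 lower and 0 higher, and 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.508 with an estimated correlation). Slc2a1, the ubiquitous glucose transporter, fell from 8.63 ± 0.10 to 7.86 ± 0.01, a 1.71-fold lower level (limma adjusted p = 0.0015). Ldha fell from 5.92 ± 0.12 to 5.53 ± 0.06 and Pdk1 from 5.34 ± 0.07 to 5.03 ± 0.07, both below the bound in both groups.

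DNA repair genes fell as a list (camera adjusted p = 0.0043, and adjusted p = 0.341 with an estimated correlation), with 5 of 17 lower and 1 higher, or 6 and 2 adjusted over the list alone. The damage kinase genes Atm and Atr fell from 3.85 ± 0.06 to 3.44 ± 0.03 and from 5.24 ± 0.08 to 4.70 ± 0.19, whereas Ercc1, of nucleotide excision repair, rose from 5.03 ± 0.09 to 5.44 ± 0.07, all below the bound in both groups. Among genes at or above the median level the repair list did not pass (camera adjusted p = 0.362). The lists of G1/S and G2/M cell cycle genes were lower with cadmium relative to other genes (camera adjusted p = 0.0083 and 0.0073). Their adjusted p = 0.637 and adjusted p = 0.679 with an estimated correlation. In the G1/S list Pola1, a DNA polymerase subunit, fell from 5.39 ± 0.14 to 4.71 ± 0.14 and Ccnd2, a cyclin, rose from 4.98 ± 0.09 to 5.41 ± 0.04, both below the bound in both groups, and 1 rose and 4 fell adjusted over the list alone. In the G2/M list 0 of 16 genes passed, also adjusted over the list alone, with Mki67 at 4.49 ± 0.08 and 4.28 ± 0.21, also below it. Without cadmium replicate 1 neither cell cycle list passed, at adjusted p of 0.101 and 0.267, nor did they among genes at or above the median level, at 0.0997 and 0.083.

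**Figure D2:**
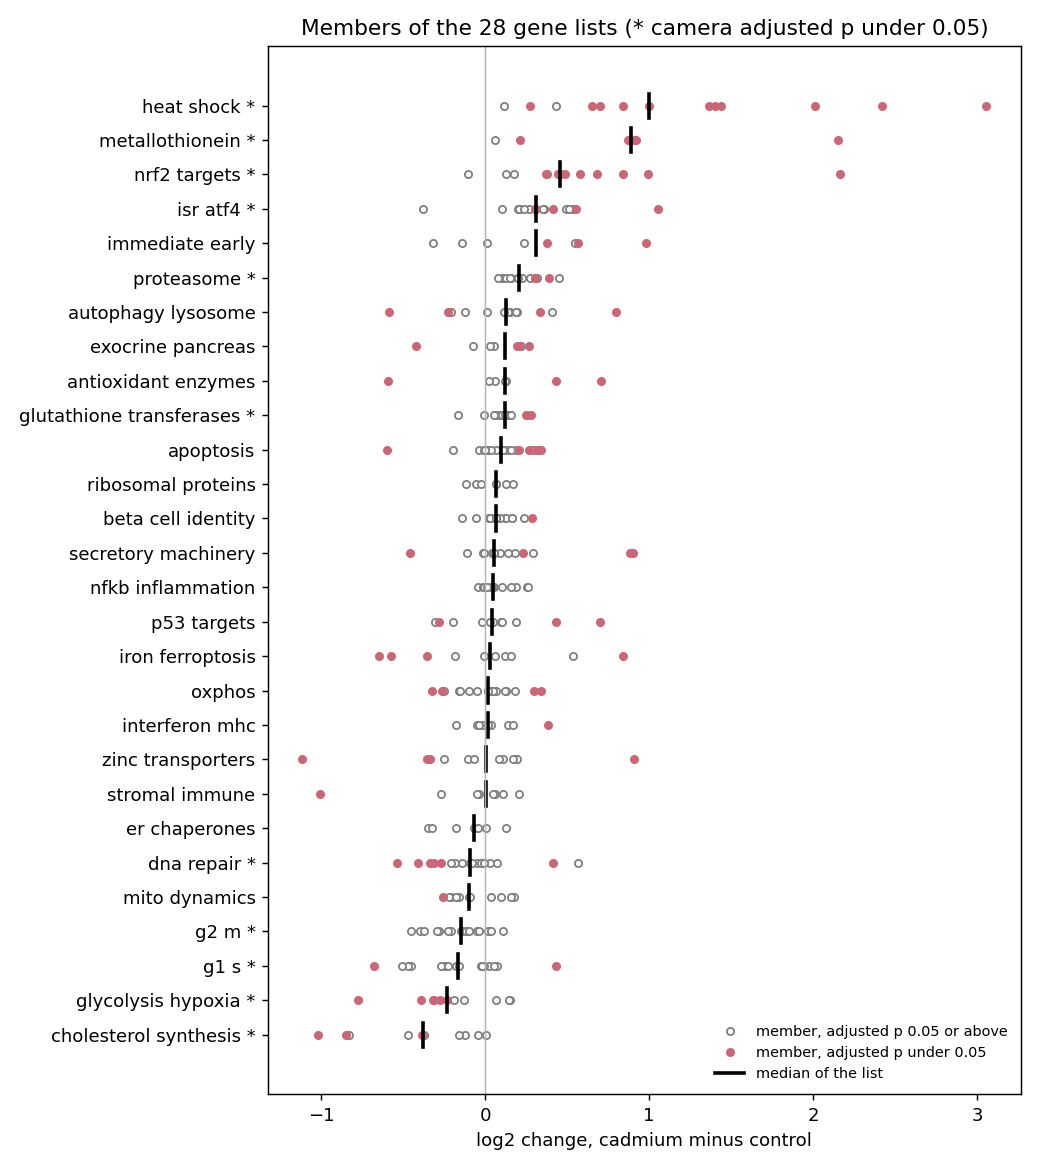
Log2 change of each measured member of the 28 tested gene lists, with filled points for members at a limma adjusted p under 0.05, open points for the others and a bar at the list's median. The x axis is cadmium minus control on the log2 scale, and lists run from heat shock, with a median of 1.00, down to cholesterol synthesis, with a median of -0.38.

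Of 17 beta cell identity genes 1 rose, and 0 did adjusted over the list alone (camera adjusted p = 0.199). The list passed fry as higher, at an adjusted p of 0.041, with a median change of 0.06 as deposited and 0.02 with each array centred. Ins2, encoding insulin, was at 5.27 ± 0.10 in control and 5.29 ± 0.04 in cadmium arrays (limma adjusted p = 0.861). Pdx1, a beta cell transcription factor, was at 4.25 ± 0.07 and 4.28 ± 0.09, Slc2a2 at 3.76 ± 0.05 and 3.82 ± 0.05, and Iapp at 1.90 ± 0.18 and 1.76 ± 0.07. All these levels were below the approximate background bound of 6.18. In the list of secretory machinery 3 of 15 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.226), and the list passed fry as higher, at an adjusted p of 0.029. Its median change was 0.06 as deposited and 0.008 with each array centred. Ptprn, a secretory granule protein, rose 1.87-fold from 6.34 ± 0.20 to 7.24 ± 0.11, and Vgf, a granule peptide precursor, rose from 4.83 ± 0.13 to 5.71 ± 0.16. The calcium channel gene Cacna1c fell from 6.41 ± 0.10 to 5.95 ± 0.08. Of the markers of other islet cells, Gcg and Ghrl were measured and did not pass, Gcg at 2.80 ± 0.04 and 2.78 ± 0.03 and Ghrl at 4.35 ± 0.02 and 4.31 ± 0.03, below the bound in both groups.

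The remaining lists did not pass the camera test. Of these, apoptosis, inflammation and exocrine pancreas passed fry as higher, at adjusted p of 0.0084, 0.022 and 0.015, and mitochondrial dynamics as lower, at 0.041. The medians of apoptosis, inflammation and exocrine pancreas were 0.096, 0.049 and 0.124 as deposited. With each array centred they were 0.048, -0.0002 and 0.075. Among zinc transporters Slc30a1 rose and Slc39a10, Slc30a9 and Slc30a7 fell, of 12 measured, and 4 rose and 4 fell adjusted over the list alone. In the apoptosis list 4 of 21 rose, including Mcl1 at 0.32 ± 0.05 (SE), and 1 fell, Aifm1, from 6.73 ± 0.11 to 6.13 ± 0.12, with 6 and 2 adjusted over the list alone. Of 8 immediate early genes 3 rose, also adjusted over the list alone, among them Mafk, from 6.11 ± 0.08 to 6.68 ± 0.09. Without cadmium replicate 1 this list passed (camera adjusted p = 0.022). Of 14 autophagy and lysosome genes 2 rose and 2 fell, also adjusted over the list alone, with Gabarapl1 going from 5.26 ± 0.13 to 6.06 ± 0.06, below the bound in both groups, and Ulk1 from 6.49 ± 0.05 to 5.91 ± 0.16. Among 12 p53 targets 2 rose, 3 adjusted over the list alone, and 1 fell, with Plk3 going from 5.26 ± 0.06 to 5.96 ± 0.25, below the bound in both groups. In the iron and ferroptosis list Slc7a11 rose, and Acsl4, Ireb2 and Lpcat3 fell, of 10, with 1 and 4 adjusted over the list alone. Of 19 oxidative phosphorylation genes 2 rose and 2 fell, also adjusted over the list alone, with Ndufs1 going from 6.07 ± 0.03 to 5.75 ± 0.03, below the bound in both groups. The stromal and immune list had 1 lower gene of 8, Col3a1, a fibrillar collagen gene, which fell from 9.07 ± 0.13 to 8.06 ± 0.17. Adjusted over the list alone 1 gene rose and 1 fell there. In the exocrine pancreas list 3 of 8 rose and 1 fell, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.438, and 0.296 to 0.637 in camera alternatives other than a filter at the median level). Among genes at or above the median level 5 of its genes were left and the list passed as higher (camera adjusted p = 0.046). Of 9 interferon and antigen presentation genes 1 rose, Bst2, also adjusted over the list alone. Of 11 mitochondrial dynamics genes 1 fell, Mff, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.074). This list passed without control replicate 1 (camera adjusted p = 0.049). Of 12 inflammation genes and 7 ribosomal protein genes 0 passed, also adjusted over the list alone. In the lists of zinc transporters, iron, oxidative phosphorylation and stromal genes the median change was above 0, at 0.01, 0.03, 0.02 and 0.005, while the camera direction was down.

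Small nuclear RNA genes made up 251 of the 1222 higher genes. Of 559 such genes 251 rose and 2 fell, 124 of them rising at least 2-fold, with a median change of 0.32 over all 559. The median was 0.27 with each array centred and 0.26 after quantile normalization. Gm23627, chosen after its values were seen, rose from 7.75 ± 0.28 to 9.60 ± 0.26. Of 11613 protein-coding genes 574 rose and 966 fell, and 20 rose and 19 fell at least 2-fold. With each array centred, 362 rose and 1321 fell, and after quantile normalization 425 rose and 1198 fell. Of 557 microRNA precursors 56 rose and 26 fell in the deposited scale, 34 rose and 39 fell with each array centred, and 41 rose and 36 fell after quantile normalization. Mir29a, Mir31 and Mir218-1 lay outside the naming rule and were chosen after their values were seen. Mir29a rose from 3.81 ± 0.81 to 7.35 ± 0.70 and Mir31 from 4.83 ± 0.19 to 6.75 ± 0.38. Mir218-1 fell from 10.43 ± 0.30 to 8.84 ± 0.09 (limma adjusted p = 0.0015).

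**Figure D3:**
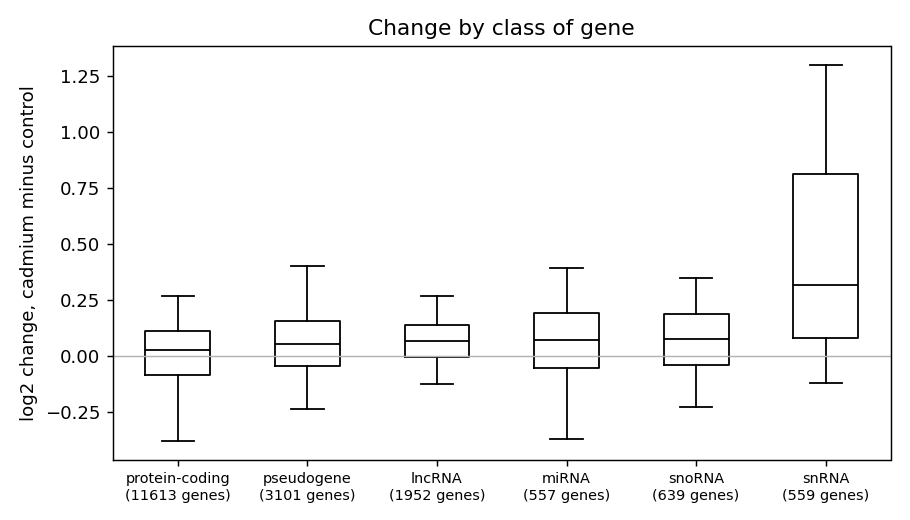
Log2 change, cadmium minus control, by class of gene. Boxes give the quartiles with the median as a line, and whiskers the 5th and 95th percentiles over genes. The small nuclear RNA box lies highest, with a median of 0.32 against 0.03 in protein-coding genes, the latter -0.02 with each array centred on its median and -0.01 after quantile normalization.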

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

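The tests in this part, except the count of splits, were chosen after the result was seen. Of 19601 transcript clusters without a gene name, which no comparison above used, 213 passed a limma adjusted p of 0.05. The largest increase among them was 1.82 and the largest decrease -2.24 on the log2 scale. The hybridisation control bioB, added at a fixed amount, was 0.429 brighter on the log2 scale in cadmium arrays, at 8.65 ± 0.07 against 8.22 ± 0.04 (SD, n = 3 each; exact permutation p = 0.1, the smallest that 3 against 3 allows). The other hybridisation controls, bioC, bioD and cre, differed by 0.251, 0.138 and -0.002. For bioC and bioD each cadmium array was brighter than any control array. The medians of positive and of negative control probes were lower on each cadmium array than on any control array, by 0.111 and 0.036. The groups overlapped in cre and in the poly-A controls dap, lys, phe and thr. Differences in controls that follow the groups cannot be told apart from treatment.

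The arrays gave 2302 changed genes in the real grouping and at most 0 in any other split of the 6 arrays into 3 and 3. The real grouping was 1 of 10 splits, too few for a share under 0.05.

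Small nuclear RNA genes were higher with cadmium in 251 cases. Better recovery of short RNAs in general, as the whole cause, is argued against by small nucleolar RNA genes. Above the negative control bound of 6.18 their median change over 42 distinct profiles was 0.008, against 1.10 over 133 of small nuclear RNA genes. The ratio was 0.00767 (bootstrap 95% interval -0.084 to 0.076). The form of this test that was run first covered all genes, most of them below the bound. It gave medians of 0.079 for small nucleolar and 0.32 for small nuclear RNA genes, a ratio of 0.249 (bootstrap 95% interval 0.182 to 0.308). Ribosomal RNA genes go with better recovery in part and leave a share of the rise open, with a median of 0.256 over all 57 genes and 0.306 over 16 distinct profiles above the bound, a ratio of 0.278 (bootstrap 95% interval 0.250 to 0.473). The bootstrap intervals in this paragraph resample genes read on the same 6 arrays. They measure the spread over genes and not that between cultures. Differences between arrays that quantile normalization removes are argued against as the whole cause by the median over all 559 genes. It was 0.32 as deposited and still 0.261 after that scaling, which lowered it most (bootstrap 95% interval 0.219 to 0.317). Centring takes the same offset of 0.049 from every gene, so its median of 0.27 was fixed beforehand and decides nothing. Identical copies do not account for the number, since the 253 called genes had 217 distinct profiles, and near-identical sequence among copies, and an effect of cadmium on these RNAs or on their polyadenylation or decay, stay open and were not tested.

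None of the beta cell identity genes, 0 of 17, lay above the negative control bound of 6.18, itself approximate. Their median level over all arrays was 4.50, against 4.44 for all protein-coding genes. They were thus low against the bound, and not against protein-coding genes in general. Few genes of any kind lay above the bound, 1146 of 11613 protein-coding genes over all arrays. Some lists exceeded other genes: in control arrays 10 of 16 proteasome genes and 6 of 7 chaperones of the endoplasmic reticulum lay above it. Of other protein-coding genes 10.3% did (Fisher exact adjusted p = 1.73e-05 and 0.00011 over 28 lists). Ribosomal protein genes, with 2 of 7 above, and oxidative phosphorylation genes, with 4 of 19, did not differ (Fisher exact adjusted p = 0.435 and 0.395). These lists were picked after levels had been seen. They do not settle whether the lack of beta cell identity genes above the bound follows from how few genes pass it. The share of mesenchymal genes, a list added after the data were seen, was not distinguishable from that of all other protein-coding genes (Fisher exact p = 1). The share of identity genes was not distinguishable from that of other protein-coding genes either (Fisher exact p = 0.247). Col3a1, at 9.07 in control arrays, had raised the question whether cells of a mesenchymal type were present, but 1 of 18 mesenchymal genes, Col5a2, lay above the bound over all arrays against 3 of 32 beta cell identity and secretory genes (Fisher exact p = 1), with 2 of 10 neuroendocrine genes, Ncam1 and Uchl1, and 0 of 9 epithelial genes. The cell type in the cultures cannot be told apart on these counts, because few genes of these 4 lists lie above the bound.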

How the results depend on the processing

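No gene or list named above that passed the threshold changed direction under any alternative run. Of the 24 genes with the largest changes 23 passed under all alternatives run for single genes, the exception being Thbs1, and of the 91 named genes that passed 48 did so. The count of changed genes was 2302, and 1385 with the replicate block (742 higher, 643 lower), 428 when tested against a change of 0.26 and 862 at an adjusted p of 0.01. Leaving out 1 array gave 1139 to 2355 changed genes, 604 to 1315 higher, 529 to 1040 lower and 53 to 85 of the named genes, and the count of changed genes was above 2302 only without cadmium replicate 1. Array weights gave 3387 changed genes, 1875 higher and 1512 lower. The 188 genes changed at least 2-fold became 108 after quantile normalization and, in an alternative added after the data were seen, 39 among protein-coding genes only, where the other classes are left out. Of the 11 lists called by camera 0 passed with an estimated correlation. Other alternatives were added after the data were seen: counting identical genes as 1 gave 2253 changed genes, and leaving out both arrays that stood apart gave 2888. Except where stated, the cause was not tested. Same-numbered arrays had correlations of deviations of -0.11, 0.06 and -0.11, and not every array correlated best with its own number. The highest correlation between groups, 0.16, was that of the arrays that stood apart. Deviations within groups this small are tied to each other, so these values cannot decide whether the numbers pair the samples. Source-name numbers, which join 2 pairs and leave out both arrays that stood apart, gave correlations of 0.07 and 0.08. With them as a block 1947 genes changed, the chaperones of the endoplasmic reticulum passed camera as lower (adjusted p = 0.00031) and immediate early genes as higher (adjusted p = 0.033), and calls such as those of Bst2 and Ndufs1 were lost. With no block and both arrays that stood apart left out, both lists passed too (camera adjusted p = 0.00018 and 0.025). That is no separate support. Each array that stood apart is alone in its source number, so both fits estimate the change from the same arrays. The block also leaves few residual degrees of freedom. The control probes limit what can be seen: 95% of negative controls lay under 6.18.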

Other observations

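The tests in this part were chosen after values had been seen. Mesenchymal, epithelial and neuroendocrine genes were tested in lists added after the data were seen. Of 18 mesenchymal genes 4 rose and 0 fell (camera adjusted p = 0.021 over the 3 lists, but adjusted p = 0.271 with an estimated correlation): Tagln, an actin-binding protein, from 4.55 ± 0.14 to 5.56 ± 0.29, Fn1, fibronectin, from 4.98 ± 0.08 to 5.48 ± 0.12, Cald1 from 5.40 ± 0.09 to 5.87 ± 0.08 and Postn from 2.59 ± 0.11 to 2.87 ± 0.05. Both group means of each of these 4 genes lay below the negative control bound of 6.18, so their changes may be compressed or uncertain. Of 9 epithelial genes 2 fell, Spint1 and St14, both also below the bound, and of 10 neuroendocrine genes 1 rose, Uchl1 (camera adjusted p = 0.073 and 0.181, and adjusted p = 0.271 and 0.480 with an estimated correlation). The only mesenchymal list member above the bound over all arrays, Col5a2, was at 6.78 ± 0.21 and 6.51 ± 0.14 and did not pass. Outside that list, and above the bound in both groups, Col3a1 fell from 9.07 ± 0.13 to 8.06 ± 0.17. Tnc, a matrix glycoprotein named after its values were seen, also lay outside it and fell from 8.05 ± 0.03 to 7.05 ± 0.06. The count of falling mesenchymal genes thus depends on how the list was drawn.

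A hypothesis was that microRNA precursors changed with the gene in whose span they lie, since Mir218-1 and its host Slit2, which went from 6.25 ± 0.05 to 5.43 ± 0.01, both fell. Over 260 host genes with 361 precursors (GRCm38.p6 spans, strand not used), the changes of precursor and host correlated across genes at Pearson r = 0.268 (permutation p = 1e-05, the smallest 100000 permutations can give) but Spearman rho = 0.0895 (permutation p = 0.152). Without the 2 hosts farthest from the median r was 0.227. Genes are not independent replicates. Where both passed the threshold, 10 of 12 pairs moved the same way. Mir218-1 and Slit2, the pair that prompted the hypothesis, are among these 10 and also entered the correlations. Host transcription may contribute for some pairs, and the rank correlation leaves open whether it does so for most.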
